A study of Mus musculus with 12 samples.

How the data were processed

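Total RNA (200 ng) from each of 12 placentas was labelled with the whole transcript sense target assay and hybridised to 1 Affymetrix Mouse Gene 1.0 ST array, per the labels' protocols. The deposited values are log2 expression values made with RMA (robust multi-array average, which corrects background, normalises between arrays and summarises probes), per the submitters' processing notes. The version of RMA, its software and the genome build are not given in the sources used here, nor is the way in which the clusters of the table were chosen. The table held 22158 transcript clusters and 12 columns, 1 per placenta, with 0 columns unassigned and 0 pairs of identical columns, and the values were used as deposited.

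The platform table gave 19125 clusters exactly 1 gene symbol, 1218 several and 1815 none. Symbols were updated through gene IDs for 19098 of the 19125 and kept as given for 27. The gene table used for names, chromosomes and the order of genes was made on GRCm38.p6, and no coordinate of it is printed. The 19125 clusters stood for 17880 symbols, of which 646 had more than 1 cluster. A cluster is named by its symbol, and where clusters of a named gene disagreed the text says so.

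Each cluster was fitted with limma as 4 group means over all 12 arrays, with empirical Bayes variances without trend or robust fitting (residual df 8, prior df 3.52). There were 7 contrasts: PTH against saline in Pth-null, in WT and averaged, Pth-null against WT under saline, under PTH and averaged, and the interaction. Tests were two-sided, with Benjamini-Hochberg adjustment over 19125 clusters and a threshold of 0.05 for the adjusted p. A group difference of a single gene or list mean was tested by exact two-sided permutation within the other factor (400 relabellings for 6 against 6), and 3 against 3 cannot go below p = 0.10. The median standard error was 0.118 log2 units for a simple contrast, 0.084 for an averaged one and 0.167 for the interaction.

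The 25 gene lists, of 713 gene entries, were fixed before the data were examined, as were the design, the alternatives and the rule for named genes except where stated. In all, 3 list symbols could not be matched to 1 gene name in the gene table or on the array. Other list genes were not measured where no cluster carried their symbol alone. Of the 25 lists, 23 were tested with limma's camera (preset correlation 0.01, 1 cluster per gene, the brightest, adjustment over the 23 lists within a contrast), with an estimated correlation and with fry beside it. The Y-linked and X-linked lists were read per array. Per-array list means were taken relative to the mean of all 12 arrays. Lists share some genes, and several tissue lists hold genes that other placental cells express too.

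Named genes were, per contrast, up to 10 per direction past the threshold with groups that did not overlap (averaged contrasts: the same sign in both parts), filled to 5 per direction by the lowest unadjusted p among clusters with at least 1.2-fold change and no overlap (interaction: no overlap condition). Up to 4 members of each list with the lowest p were available for naming, and key genes of PTH action, mineral transport and sex were named throughout. Predicted models, clones, olfactory and vomeronasal receptors and gene families of unknown function were passed over (symbols with Gm and a number, Rik, LOC, Olfr, Vmn, OTT, EG, D with Ert, clone numbers beginning BC, AI, AU, C or DQ, and Ssx). The symbol patterns for these were edited after values had been seen: small nucleolar RNAs, antisense genes and several known families, passed over at first, became nameable, and Ssx9 was passed over after it had appeared among the genes higher after PTH in Pth-null placentas, which let Duox2 in. Olfr804, Alb, Ugt2b34, Lgals2, Lsm5, Trim30d and 9130019O22Rik were named after their values were seen.

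The steps were tested on 20 simulated data sets of 19125 genes, of which 200 changed. For PTH in Pth-null placentas, 41.6% of genes changed by 0.5 log2 units, 93.4% of those changed by 1 and 99.2% of those changed by 2 were called, with 4.6% false calls. For the averaged genotype contrast these shares were 79.6%, 98.9% and 99.7%, with 4.9% false. A list of 30 genes shifted by 0.3 was called in 100% of sets and an unshifted one in 0%, with genes simulated as independent. Many changed genes make the adjusted threshold easier to pass, and the simulated arrays shared no structure between genes. In the real contrasts at most 3 clusters passed. The simulated shares therefore do not tell how many real changes of these sizes would be called.

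Alternatives were centring on medians, a second quantile normalization, clusters above the median level, all clusters, only the groups compared, trend and robust variances, array weights, the replicate number as a block, covariates for Y-linked, decidual and yolk sac means, an adjusted p under 0.10, genes flanking Pth left out, and each array left out; list tests were also run with the mean of all clusters of a gene. Chosen after the data were seen were the Y-linked and yolk sac covariates together, the fit without 3 arrays whose yolk sac mean was over 0.5 under the mean of all 12 (a limit set after the means were seen), and all covariates in list tests. Arrays were called as having Y-linked transcripts at an Eif2s3y value over 5, also set after the values were seen. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.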

Results

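Gene expression was measured in 12 mouse placentas on embryonic day 18.5, with 1 Affymetrix Mouse Gene 1.0 ST array per placenta. The fetuses were wild type (WT) or lacked Pth, the gene of parathyroid hormone (PTH), a peptide hormone that raises blood calcium. Each fetus received an intraabdominal injection in utero of 1 nmol full-length PTH in 2 µl saline or of 2 µl saline, and its placenta was collected 90 minutes later. There were 3 placentas in each of 4 groups: WT saline, WT PTH, Pth-null saline and Pth-null PTH. Array medians lay between 6.73 and 6.78 log2 units, and the number of arrays limits the precision: the median 95% half-width was 0.26 log2 units for a difference of 2 groups, 0.18 for an averaged difference and 0.37 for the interaction. The labels do not tie placentas to litters or dams, so p-values measure the spread between these samples.

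Pth was read at 2.56 to 3.00 log2 units on the 12 arrays, a level that only 2.8% of clusters lay under. Its mean was 2.86 in WT saline, 2.67 in WT PTH, 2.92 in Pth-null saline and 2.66 in Pth-null PTH placentas (n = 3 each). The genotypes differed by 0.03 (SE 0.06, adjusted p = 1) averaged over treatments. At a level this near the floor of the table, the gene does not check the genotype labels.

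The genotype comparison asks which placental transcripts depend on fetal Pth. Pth-null placentas held less RNA of 3 genes than WT placentas when both treatments were averaged. Trim12a, a tripartite motif gene on chromosome 7, fell by 1.78 log2 units (SE 0.10, 3.43-fold, adjusted p = 2.2e-05), from 6.50 ± 0.21 (SD, n = 6) in WT to 4.73 ± 0.20 in Pth-null arrays. Pgc, which encodes the aspartic protease precursor progastricsin, fell by 1.69 (SE 0.14, 3.24-fold, adjusted p = 0.00042), from 8.10 ± 0.10 to 6.41 ± 0.34. Dmgdh, the mitochondrial dimethylglycine dehydrogenase of choline breakdown, fell by 1.13 (SE 0.09, 2.19-fold, adjusted p = 0.00042), from 7.18 ± 0.21 to 6.05 ± 0.19. For each of the 3 genes, all 6 Pth-null arrays lay under all 6 WT arrays (exact two-sided permutation p = 0.005 each, the smallest that relabelling genotype within treatments allows). The 3 genes were chosen from 19125 clusters by the same arrays, so this test adds no separate support. Fabp1 and Slc14a1, not past the threshold, also reached p = 0.005 by this permutation test. Trim12a has close paralogs in the same cluster of tripartite motif genes, and whether its probes also bind their transcripts was not tested.

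No gene was past the threshold in the other direction in this fit, while some passed in other settings. Those with the lowest p among higher genes not past it included Fabp1, the liver fatty acid binding protein, at 1.22 (SE 0.18, adjusted p = 0.11), and Stard10, a lipid transfer protein, at 0.49 (SE 0.07, adjusted p = 0.10). Trim34a, another tripartite motif gene, stood at 0.61, the synaptotagmin Syt9 at 0.48 and the tetraspanin Tspan12 at 0.38, with adjusted p from 0.25 to 0.49. On the lower side, the urea transporter Slc14a1 had an estimate of -0.77 (adjusted p = 0.11) and Aifm3, of the apoptosis-inducing factor family, one of -0.60 (adjusted p = 0.17). By limma, 3 of 19125 clusters passed and 579 had an unadjusted p under 0.05, where chance gives 956. The count was 1 among clusters above the median level, a set that leaves out Trim12a and Dmgdh, 4 with array weights, 6 with trend and robust variances (2 higher, 4 lower), 10 with the yolk sac mean as a covariate (4 higher, 6 lower) and 6 with the Y-linked and yolk sac means as covariates (1 higher, 5 lower). The higher ones with the yolk sac covariate were the glucuronosyltransferase Ugt2b34 at 1.07 (adjusted p = 0.0048), the galectin Lgals2 at 0.81 (0.035), Stard10 at 0.49 (0.049) and Trim34a at 0.62 (0.049), and Ugt2b34 also passed with both covariates (1.08, 0.016). Stard10 passed with trend and robust variances (0.00474) and array weights (0.0349) too, and Fabp1 with trend and robust variances (0.0292). Slc14a1 passed with trend and robust variances (0.0218), the yolk sac covariate (0.0168) and both covariates (0.0333). Fabp1 also passed without Pth-null PTH replicate 3 (1.02, adjusted p = 0.000907).

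**Figure D1:**
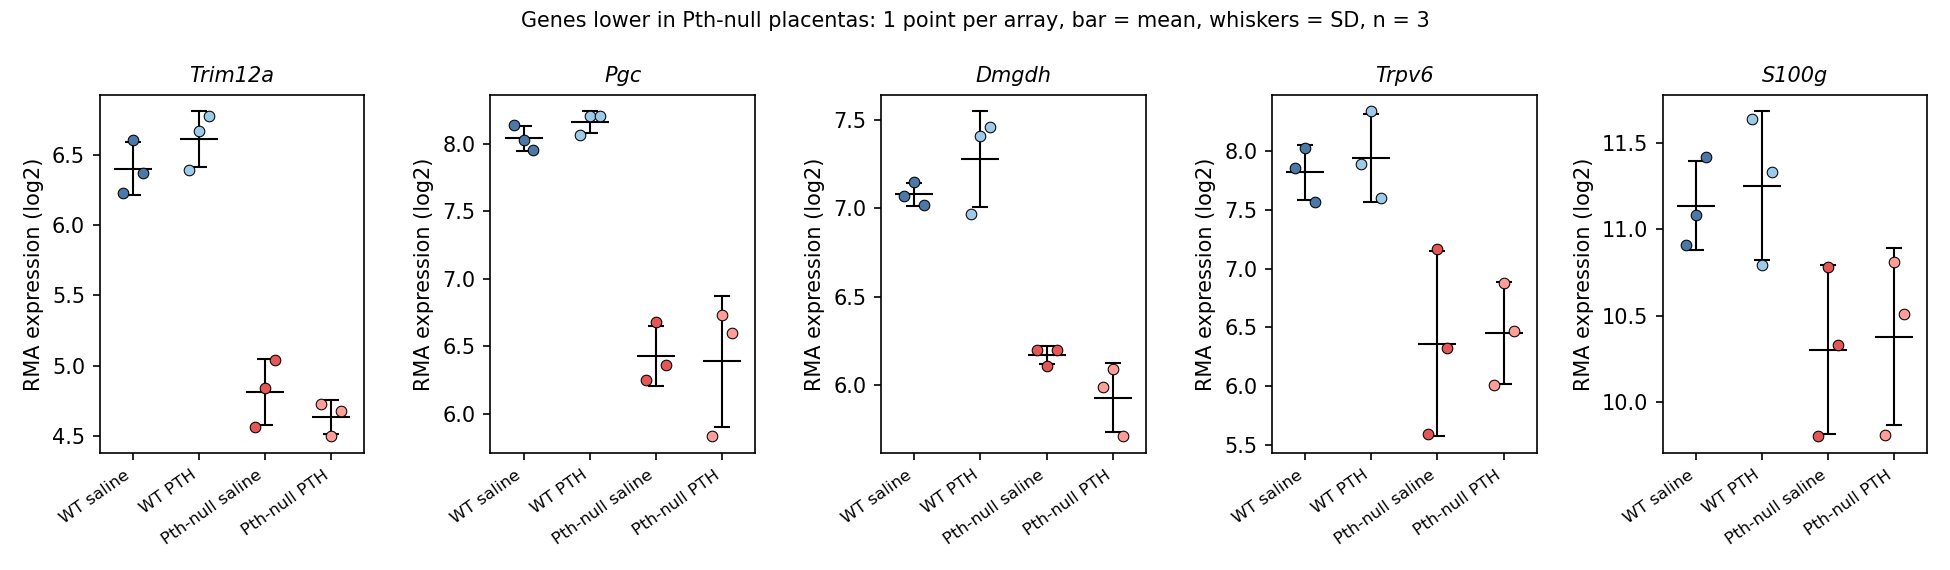
Log2 RMA expression of Trim12a, Pgc, Dmgdh, Trpv6 and S100g (y axes, scales differ) in the 4 groups (x axis), with 1 point per array, the mean as a bar and the SD as whiskers (n = 3). All 6 Pth-null arrays lie under all 6 WT arrays for Trim12a, Pgc, Dmgdh and Trpv6, and S100g overlaps slightly (highest Pth-null 10.81, lowest WT 10.79).

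Genes of calcium transport were examined as a list of 50 fixed genes, of which 45 were measured. Trpv6, the epithelial calcium entry channel, had an averaged difference of -1.48 (SE 0.25) and a mean of 7.88 ± 0.29 in WT and 6.41 ± 0.57 in Pth-null arrays (SD, n = 6). S100g, the calcium binding protein calbindin-D9k, had a difference of -0.86 (SE 0.21), with 11.19 ± 0.32 in WT and 10.34 ± 0.45 in Pth-null arrays. Neither passed over all clusters (adjusted p = 0.17 and 1), and both passed adjusted over the list alone (0.0032 and 0.042); 0 members rose and 2 fell by that count. The exact two-sided permutation p was 0.005 for Trpv6 and 0.01 for S100g. The plasma membrane calcium pump Atp2b1 stood at -0.13 and the store-operated calcium sensor Stim1 at -0.17, and neither passed. Trpv6 passed over all clusters without Pth-null saline replicate 2 (-1.68, adjusted p = 0.026), with the replicate number as a block (0.0256) and with the yolk sac covariate (0.049), and S100g with the Y-linked and yolk sac covariates together (0.0349). The list as a whole did not pass (camera adjusted p = 0.22; 0.95 with an estimated correlation; 0.98 by fry). No list passed in this contrast (lowest adjusted p = 0.14), with 3 at an unadjusted p under 0.05.

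Other genes of mineral handling did not differ between genotypes past the threshold. The magnesium channel Trpm6 had an averaged difference of -0.28 (SE 0.11) and the magnesium transporter Slc41a1 one of 0.03 (SE 0.08). The PTH receptor Pth1r stood at -0.09, the calcium-sensing receptor Casr at -0.02, the vitamin D receptor Vdr at 0.01 (SE 0.77) and the vitamin D activating enzyme Cyp27b1 at 0.12. Pthlh, Cyp24a1, Gcm1 and Ddx3y had no cluster with their symbol and were not analysed here. Among 42 measured genes flanking Pth on chromosome 7, 0 passed over all clusters, while Tmc7, a transmembrane channel-like gene, had a difference of 0.40 (0.042 adjusted over the list alone).

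Under saline, 2 clusters were lower and 0 higher in Pth-null placentas. Trim12a fell by 1.58 (SE 0.14, adjusted p = 0.0035), from 6.40 ± 0.19 to 4.82 ± 0.24 (SD, n = 3), and Pgc fell by 1.61 (SE 0.20, adjusted p = 0.035), from 8.04 ± 0.09 to 6.43 ± 0.22. Dmgdh had an estimate of -0.91 that did not pass (adjusted p = 0.13), with 7.08 ± 0.06 in WT and 6.17 ± 0.05 in Pth-null placentas. Others not past the threshold (adjusted p = 0.99) were Stard10 at 0.51, Tmc7 at 0.57 (0.038 adjusted over the list alone), the lipase-like Abhd3 at 0.40, the guanine nucleotide exchange factor Dock6 at 0.42, Sval2 at 0.48, the myeloid transcription factor Cebpe at -0.43 and the pentraxin-like Mptx1 at -0.54. The Dock6 value is 1 of 15 clusters of the gene, which ranged from -0.07 to 0.42. Trpv6 stood at -1.46 (0.06 adjusted over the list alone), S100g at -0.83 (0.22) and Crem at 0.32. By limma, 794 clusters had an unadjusted p under 0.05, and 7.8% of clusters had groups that did not overlap, where chance gives 10%. The Pgc call ended without any of WT saline replicates 1, 2 and 3, WT PTH replicates 1, 2 and 3 or Pth-null saline replicates 1 and 3 (adjusted p = 0.0512 to 0.32), or with the Y-linked covariate, alone (-1.64, adjusted p = 0.0933) or with the yolk sac one (-1.53, 0.0526), while its change stayed between -1.74 and -1.52 over all settings run. Dmgdh passed without WT PTH replicate 1 (adjusted p = 0.0223), with trend and robust variances (0.0381) and with only the arrays compared (0.0437), and the count was 3 without Pth-null saline replicate 2 (adding Olfr804) or Pth-null PTH replicate 3 (adding Fabp1).

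Under PTH, 3 clusters were lower and 0 higher in Pth-null placentas. Trim12a fell by 1.97 (adjusted p = 0.00032), from 6.61 ± 0.20 to 4.64 ± 0.12, Pgc by 1.78 (adjusted p = 0.0086), from 8.16 ± 0.08 to 6.39 ± 0.48, and Dmgdh by 1.35 (adjusted p = 0.0037), from 7.28 ± 0.27 to 5.93 ± 0.19 (SD, n = 3). Genes not past the threshold were Fabp1 at 1.37, the exocytosis protein syncollin (Sycn) at 0.70, the sperm protein Eqtn at 0.44, Stard10 at 0.47, the inflammasome gene Nlrp1b at 0.38, Slc14a1 at -1.01 and Aifm3 at -0.67, with adjusted p from 0.33 to 1. Trpv6 stood at -1.49 (0.05 adjusted over the list alone, not under the threshold) and S100g at -0.88 (0.31). The water channel Aqp8 stood at -1.08 and the transferrin receptor Tfrc at -0.82, and neither passed. By limma, 710 clusters had an unadjusted p under 0.05, and 8.3% had groups that did not overlap, where chance gives 10%. The Pgc call ended without WT PTH replicate 2 (adjusted p = 0.0809) or replicate 3 (0.0785), and the count fell to 1 (Trim12a) with only the arrays compared. Without the 3 arrays poorest in yolk sac transcripts, which leaves 1 WT PTH array assumed to vary like the others, it fell to 0, with Trim12a at -1.80, Pgc at -1.41 and Dmgdh at -1.07 (adjusted p = 0.321, 0.321 and 0.772). The changes under saline and under PTH had a correlation of -0.17 across genes, which are not independent replicates.

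The injection of PTH into Pth-null fetuses asks what the hormone does in placentas of fetuses without their own supply. No cluster passed in Pth-null placentas (limma, lowest adjusted p = 1), and 443 had an unadjusted p under 0.05, of which 242 were higher and 201 lower. Among genes with higher readings, the lowest p went with Tppp3, a tubulin polymerisation protein, at 0.66, the autophagy receptor Calcoco2 at 0.68, the kinesin Kif26b at 0.47 (0.11 in its other cluster), the lysyl oxidase-like Loxl4 at 0.40 and the dual oxidase Duox2 at 0.37. Among genes with lower readings, it went with the chemokine Ccl6 at -0.65, the pentraxin Ptx3 at -0.50, Iqcf4 at -0.50, Lyrm7 at -0.33 and A1bg at -0.29. The mineral genes stood at 0.09 for Trpv6, 0.08 for S100g, 0.01 for Atp2b1, 0.00 for Trpm6, -0.05 for Slc41a1 and -0.05 for Pth1r. Groups did not overlap in 6.1% of clusters, where chance gives 10%. With the yolk sac mean as a covariate Tppp3 passed (0.70, adjusted p = 0.042), and without Pth-null saline replicate 2 the count was 1, the olfactory receptor Olfr804.

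The immediate early and cAMP lists, which PTH signalling could reach, gave small estimates in Pth-null placentas. So did the decidual list, which was fixed as a check of dissection and cell types. Of 31 measured immediate early genes, 29 had positive estimates and 0 passed singly, with a median of 0.13 and examples Junb at 0.27, Ier2 at 0.37, Myc at 0.27 and Dusp1 at 0.26. Of 29 measured cAMP and CREB target genes, 22 were positive and 0 passed singly, with Nr4a1, an orphan nuclear receptor induced by cAMP, at 0.63, the gluconeogenic enzyme Pck1 at 0.52, Crispld2 at 0.46 and somatostatin (Sst) at 0.32. Of 34 genes of decidua, myometrium and uterine natural killer cells, 24 were positive and 0 passed singly, with the collagen Col1a1 at 0.50 and the smooth muscle actin Actg2 at 0.58. With a preset correlation, camera called the 3 lists higher (adjusted p = 2.3e-06, 0.0045 and 0.04), and none held: each had adjusted p = 0.92 with an estimated correlation and 0.98 by fry. The immediate early call ended without Pth-null PTH replicate 3 (adjusted p = 0.37), the cAMP call without that array (0.37) or Pth-null saline replicate 2 (0.30), and the decidua call without either of them or Pth-null saline replicate 1 or Pth-null PTH replicate 1 (0.057 to 0.56).

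In WT placentas no cluster passed after PTH (limma, lowest adjusted p = 0.837), and 1086 had an unadjusted p under 0.05, of which 341 were higher and 745 lower. Positive estimates with the lowest p were Slc14a1 at 0.70, the peptidase Naalad2 at 0.57, the small nucleolar RNAs Snord35b at 0.47 and Snord15a at 0.43 and the telomere protein Tinf2 at 0.44. Negative estimates with the lowest p were the interferon gene Ifnab at -0.89, the collagen Col8a2 at -0.57, Eqtn at -0.43, the cadherin Cdh18 at -0.42 and Saxo2 at -0.38. Trpv6 stood at 0.13, S100g at 0.12, Casr at -0.30 and Vdr at -0.87 (SE 1.09). Crem, a transcription factor of the cAMP response, stood at 0.32, the G protein regulator Rgs2 at 0.42, Nr4a1 at 0.49 and Fos at 0.05, and none passed. Groups did not overlap in 9.6% of clusters, where chance gives 10%.

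Of 29 measured yolk sac genes, 23 had negative estimates in WT placentas after PTH, with a median of -0.86 and examples Cubn at -1.64, the transferrin gene Trf at -1.45 and the fibrinogen chain Fgb at -2.26. No member passed singly. Camera with a preset correlation called the list lower (adjusted p = 0.024), which did not hold (adjusted p = 0.84 with an estimated correlation, 0.77 by fry). The call ended without WT saline replicate 2 (adjusted p = 0.24), WT saline replicate 3 (0.086) or WT PTH replicate 3 (0.78). Without the 3 arrays poorest in these transcripts the sign turned (0.002), but that leaves 1 WT PTH array, the one with the highest mean of its genotype (0.89), and the arrays were chosen by this same mean.

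Averaged over genotypes, PTH left 0 clusters past the threshold (limma, lowest adjusted p = 1), with 599 at an unadjusted p under 0.05. The lowest p among positive estimates went with the keratin Krt1 at 1.19, Crxos at 0.60, Naalad2 at 0.43, Tinf2 at 0.38 and Calm5 at 0.35, and among negative ones with Ifnab at -0.50, Ptx3 at -0.39, Trim31 at -0.35, Impg1 at -0.32 and A1bg at -0.27. Trpv6 stood at 0.11 (SE 0.25), S100g at 0.10 (SE 0.21) and Atp2b1 at 0.02 (SE 0.07). Nr4a1 stood at 0.56 (exact two-sided permutation p = 0.06), with 10.01 ± 0.51 after saline and 10.57 ± 0.27 after PTH (SD, n = 6).

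Of the cAMP and CREB target genes 24 of 29 had positive averaged estimates, among them Nr4a1, the leucine zipper factor Nfil3 at 0.21 and the hyaluronan synthase Has2 at 0.52. Of the immediate early genes 27 of 31 were positive, with Cebpd at 0.31, Myc at 0.24 and Dusp1 at 0.21. With a preset correlation camera called both higher (adjusted p = 7.3e-05 and 7.2e-05), with the endothelial list (20 of 21 positive, 0.0052), the decidual list (25 of 34, 0.017) and the heat shock list (20 of 25, 0.017), and the yolk sac list lower (21 of 29 negative, 0.023). None held with an estimated correlation (adjusted p = 0.74 for each but the yolk sac list, which had 0.85) or by fry (0.91 and 0.94). With the preset correlation, the cAMP and immediate early calls stayed with each array left out (highest adjusted p = 0.021 and 0.037). That preset, 0.01, takes list members as nearly unrelated. Within groups, their median r with the rest of the list was 0.52 and 0.66. As a mean per array, the cAMP list was 0.13 higher after PTH (exact two-sided permutation p = 0.03, adjusted p = 0.69 over 23 lists). Without WT PTH replicate 3 the endothelial, decidual, heat shock and yolk sac lists had adjusted p = 0.19, 0.19, 0.18 and 0.63. The endothelial call also ended without WT saline replicate 3 (0.083) or Pth-null PTH replicate 1 (0.085), the heat shock call without WT PTH replicate 1 (0.056), Pth-null saline replicate 2 (0.11) or Pth-null PTH replicate 3 (0.26), the decidual call without WT saline replicate 3 (0.097), WT PTH replicate 1 (0.056), Pth-null saline replicate 1 (0.15), Pth-null PTH replicate 1 (0.28) or Pth-null PTH replicate 3 (0.11), and the yolk sac call without WT saline replicate 2 (0.24), WT saline replicate 3 (0.07), WT PTH replicate 2 (0.08), Pth-null saline replicate 2 (0.41) or Pth-null PTH replicate 1 (0.81).

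The interaction asks whether PTH acted differently in the 2 genotypes. No cluster passed (limma, lowest adjusted p = 0.935), and 992 had an unadjusted p under 0.05. Genes with the lowest p and a positive estimate were the secreted factor Fam3b at 0.81, Col8a2 at 0.73, Ppifos at 0.60, Ect2l at 0.59 (1 of 13 clusters of the gene, which disagree, from -0.50 to 0.63) and the NAD hydrolase Sarm1 at 0.54. Those with a negative estimate were Ccl6 at -0.89, Sval2 at -0.67, Zup1 at -0.64, the homeobox gene Hoxc6 at -0.56 and the amino acid transporter Slc38a9 at -0.42. Crem stood at -0.45, Pck1 at 0.68 and Fgf23 at 0.62, and Trpv6 and S100g at -0.04 each (SE 0.49 and 0.43). No list passed (camera, lowest adjusted p = 0.14; 0.93 with an estimated correlation; 0.94 by fry), with 4 lists at an unadjusted p under 0.05.

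Transcripts of the intraplacental and visceral yolk sac, which are fetal membranes, were read with a single list. Its mean had the widest spread within groups among the 23 lists tested (pooled SD 0.94, next 0.23). The mean of the list relative to all 12 arrays was 0.48 ± 0.18 in WT saline, -0.39 ± 1.15 in WT PTH, 0.06 ± 0.59 in Pth-null saline and -0.14 ± 1.35 in Pth-null PTH (SD, n = 3). Afp, the fetal serum protein alpha-fetoprotein, ranged from 10.03 to 13.75 and albumin (Alb) from 4.93 to 12.13. WT PTH replicates 2 and 3 and Pth-null PTH replicate 1 had the lowest means (-0.70, -1.35 and -1.66). The first principal component held 33.2% of the variance and had r = -0.93 with this mean. Vdr followed the yolk sac mean over the 12 arrays (Pearson r = 0.93, Spearman rho = 0.99, permutation p = 1e-05 for each, the smallest 100000 resamples can give, adjusted p = 8e-05 over 8 genes). Without the 2 farthest arrays r was 0.97, and within groups it was 0.97. S100g (r = 0.47, adjusted p = 0.32) and Trpv6 (r = 0.27, adjusted p = 0.51) did not pass over all arrays. After group means were removed their r was 0.79 and 0.56, and over Pth-null arrays alone 0.89 and 0.74, values that were not tested. The difference between PTH and saline in the list mean was -0.53 (exact two-sided permutation p = 0.32).

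**Figure D2:**
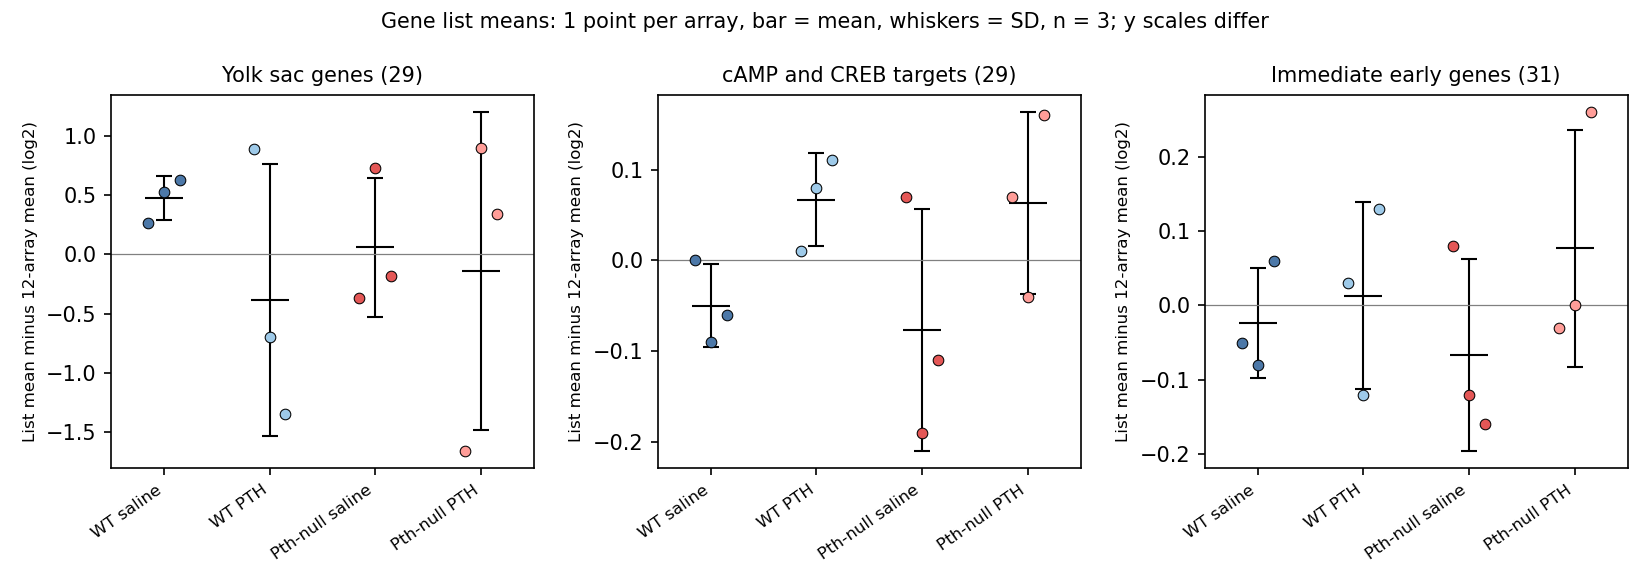
Mean of the yolk sac, cAMP and immediate early lists per array, in log2 units relative to the mean of all 12 arrays (y axes, scales differ), in the 4 groups (x axis), with 1 point per array, the mean as a bar and the SD as whiskers (n = 3). The yolk sac means of the PTH groups spread widely, with an SD of 1.15 and 1.35.

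The labels give the sex of every sample as female without saying whether dam or fetus is meant. Eif2s3y, a translation factor gene of the Y chromosome, was read at 7.55 to 8.26 on 6 arrays and at 2.63 to 3.23 on the others. Xist, the RNA that silences 1 X chromosome in female cells, was at 7.60 to 8.14 on the former and at 10.30 to 10.49 on the latter. The arrays with Y-linked transcripts numbered 2 of 3 in WT saline, 1 of 3 in WT PTH, 1 of 3 in Pth-null saline and 2 of 3 in Pth-null PTH placentas. The interaction is therefore partly mixed with sex: Eif2s3y stood at 3.36 in it (SE 2.8).

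**Figure D3:**
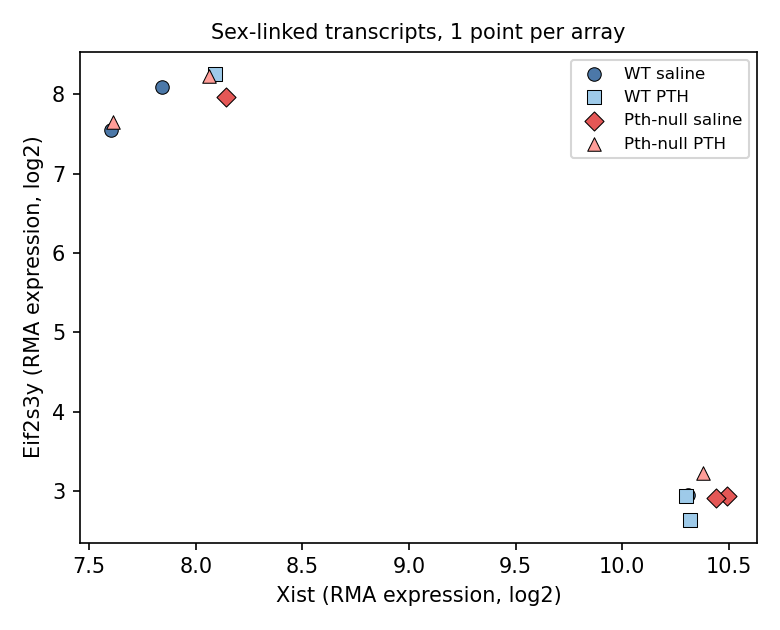
Log2 RMA expression of the Y-linked gene Eif2s3y (y axis) against Xist (x axis), with 1 point per array and 1 symbol per group. The 6 arrays with Eif2s3y at 7.55 or more have Xist at 8.14 or less, and the others have Xist at 10.30 or more.

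The remaining lists were past the threshold in no contrast by camera with a preset correlation. The lowest adjusted p over the 7 contrasts was 0.065 for PTH receptor signalling genes, 0.091 for amino acid, glucose and lipid transport, 0.094 for placental calcium transport, 0.10 for spongiotrophoblast and glycogen cells, 0.11 for genes flanking Pth and 0.18 for erythroid cells. It was 0.23 for imprinted genes and for glucocorticoid and interferon response genes, 0.28 for leukocytes, 0.38 for other cation channels, 0.66 for the cell cycle and 0.70 for the PTH and vitamin D axis. It was 0.37 for each of the lists of magnesium transport, phosphate transport, labyrinth, giant cells, and hypoxia and glycolysis. No list of any contrast passed with an estimated correlation or by fry. Under saline 0 lists passed between genotypes (lowest adjusted p = 0.065, 3 at an unadjusted p under 0.05), and under PTH 0 (0.10, 2). Leaving out 1 array gave 0 to 3 lists under saline, 0 to 4 under PTH, 0 to 5 averaged over treatments and 0 to 3 in the interaction.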

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

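The tests of Xist below were chosen after the Y-linked values had been seen. Y-linked transcripts drew attention because the comparisons do not use them and every sample is labelled female: 6 of the 12 arrays had Eif2s3y at 7.55 to 8.26, while the others had at most 3.23. RNA of male samples carried over into female ones would leave Xist high, but the lowest Xist of the arrays without Y-linked transcripts lay 2.16 log2 units above the highest of those with them, which argues against carry-over. The gap is what placentas of male fetuses would show, with Xist from maternal tissue remaining. The labels may give the sex of the dam, which was not tested.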

How the results depend on the processing

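Covariates in list tests, the 2 covariates together and the fit without the 3 arrays poorest in yolk sac transcripts were chosen after the data were seen. Averaged over treatments, Trim12a, Pgc and Dmgdh stayed lower in Pth-null placentas past the threshold in every setting that tested them (highest adjusted p 0.0039, 0.0039 and 0.025). The count of 3 was 1 above the median level, where fewer genes are tested, 6 with trend and robust variances, 10 with the yolk sac covariate, 6 with both covariates, and 3 to 4 with 1 array left out. Under saline the count of 2 was 1 above the median level, 1 with the Y-linked covariate, 1 with both, 3 with trend and robust variances or only the arrays compared (each adding Dmgdh), 3 with the decidual covariate (adding Lsm5), and 1 to 3 with 1 array left out. Under PTH the count of 3 was 1 above the median level, 1 with only the arrays compared, 0 without the 3 arrays, which leaves 1 WT PTH array assumed to vary like the others (Trim12a -1.80, against -1.97 with all arrays), and 2 to 3 with 1 array left out. PTH gave 1 with the yolk sac covariate in Pth-null placentas (0 to 1 with 1 array left out), and 0 to 0 with 1 array left out in WT, averaged and in the interaction. With the replicate number as a block the counts were 0 and 0 for PTH in Pth-null and WT, 2 and 3 for genotype under saline and PTH, 0 for the interaction and 0 and 4 for the averaged PTH and genotype contrasts. The replicate numbers were not taken to pair the samples. Of 18 pairings of equal numbers, 4 had r over 0.1 (-0.62 to 0.43), and 3 of 12 arrays had their best match under the same number. Pairing by litter or dam stays open, since the labels do not give it. Of single named genes and list members, 10 values lost and 3 gained a call under saline, 7 lost one for genotype under PTH, 14 gained one for genotype averaged and 1 for PTH in Pth-null placentas, and 0 called values reversed. List counts moved more. A list used as a covariate was left out of its own test, so counts with the yolk sac or decidual covariate cover 1 list fewer. For PTH in Pth-null placentas, 3 lists became 0 with an estimated correlation and 0 by fry, 5 above the median level, 5 with the Y-linked covariate, 1 with the decidual one (2 of the 3 lists tested), 5 with both, and 2 to 7 with 1 array left out. In WT, 1, the yolk sac list, became 0 with an estimated correlation, by fry and with the decidual covariate; with the yolk sac covariate it was not tested, and 0 of the others passed (with both, 1, the leukocyte list). The count was 2 without the 3 arrays, and 0 to 4 with 1 array left out. Averaged, 6 became 0 with an estimated correlation, 0 by fry, 2 with the yolk sac, decidual or both covariates (5 of the 6 tested in each), and 2 to 7 with 1 array left out. For genotype, 0 became 5 above the median level, 2 with the Y-linked covariate and 2 without the 3 arrays under saline (0 to 3 with 1 array left out), 1 with the replicate block, 1 with the Y-linked covariate and 3 with both under PTH (0 to 4), and 1 without the 3 arrays when averaged (0 to 5). For the interaction 0 became 3 above the median level, 3 with the Y-linked covariate, 3 with both, and 0 to 3 with 1 array left out. The yolk sac list turned to higher after PTH without the 3 arrays (adjusted p = 7e-10 in Pth-null, 0.002 in WT, 1e-09 averaged) and in Pth-null without Pth-null PTH replicate 1 (9.3e-05). The first 3 follow from construction, since the 3 arrays, all given PTH, were chosen by the mean of that list. For the other moves the cause was not tested. Signal over background limits genes such as Pth, read near the floor.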

Other observations

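Several genes of other placental functions had lower or higher readings in Pth-null placentas without passing the threshold over all clusters. Averaged over treatments, the water channel Aqp8 stood at -1.16, the transferrin receptor Tfrc at -0.56, the imprinted growth regulator Phlda2 at -0.32 and the embryonic globin Hbb-y at 0.67. Aqp8, Phlda2 and Hbb-y lie on chromosome 7, as Pth does, and Tfrc on chromosome 16. Whether a chromosome segment carried along with the null allele changed these genes was not tested. Aqp8 passed with the yolk sac covariate (-1.11, adjusted p = 0.0485). Averaged over genotypes, Slc14a1 was 0.46 higher after PTH (exact two-sided permutation p = 0.015), a gene chosen here after its values were seen. No cluster was past the threshold in that contrast. With the yolk sac covariate the Slc14a1 estimate for PTH was 0.56 in WT and 0.18 in Pth-null placentas.

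The tests of chromosome 7, of the yolk sac and of sex below were chosen after the results were seen, while the splits of the samples and the relation of the 2 genotype comparisons were planned before. Pth lies on chromosome 7, and a segment carried along with the null allele from another strain could change genes around it. Of 26 clusters with unadjusted p under 0.001 for genotype averaged over treatments, 8 (30.8%) were on chromosome 7, against 8.6% of all clusters (Fisher's exact p = 0.0011, two-sided): Trim12a, Trim34a, Trim30d, Stard10, Syt9, Sycn, Tmc7 and 9130019O22Rik. Fisher's test takes clusters as independent, while Trim12a, Trim34a and Trim30d are close neighbours, 173 to 182 protein-coding genes from Pth. The mean of the list of genes flanking Pth differed by 0.01 between genotypes (exact two-sided permutation p = 0.845), a measure in which rises and falls cancel. Of 100 relabellings of genotype, 8 gave as many chromosome 7 clusters (highest other 17); by the one-sided Fisher p, a measure added after that count had been seen, only the real one reached 0.0011 (lowest other 0.017). Trim12a lies 180 protein-coding genes from Pth and Tmc7 26, while Sycn lies 1021 away, so a carried segment stays open for Trim12a, as do a strain difference in probe binding and an effect of Pth.

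None of Pgc, Dmgdh, Trpv6 and S100g lies on chromosome 7 (0 of 4), which argues against a segment around Pth altering them by its own sequence. Averaged over treatments, yolk sac share, as read by the list mean, and fetal sex were both balanced between genotypes. Within treatments they were not. The yolk sac difference was -0.42 under saline and 0.25 under PTH, and Y-linked transcripts were on 1 Pth-null and 2 WT arrays under saline and on 2 and 1 under PTH. The averaged balance argues against both as the whole cause of the averaged changes in Pgc, Dmgdh, Trpv6, S100g and Trim12a. The list mean followed 22 of its 29 members, so it does not speak for the others. The yolk sac means of the genotypes differed by -0.09, which gives at most 6.2% of any of the 5 changes at the steeper end of the 95% interval of its slope within groups. The Pth-null and WT arrays with Y-linked transcripts numbered 3 of 6 each, a difference of 0. The 3 calls averaged over treatments exceeded what most splits gave. As many came from 4 of 100 splits, the real one included, under the limit of 5 planned beforehand. The others of the 4 gave more calls (148, 32 and 5), so this count does not exclude chance. The split with 148 points to a structure of the samples. Its sides differed by -1.22 in the yolk sac mean and the real ones by -0.09. Litter and strain background were not tested, so an effect of Pth on these genes may be right but stays a hypothesis.

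Under saline 2 clusters passed (highest other split 0) and under PTH 3 (highest other 249), and 10 splits are too few for a share under 0.05. The split with 249 points to a structure of the samples: of the 10 it had the largest difference in the yolk sac mean (-1.95, real 0.25), a comparison made after the counts were seen. The genotype changes under saline and under PTH had r = -0.17 across genes, and 75 of 100 relabellings gave one as high (highest other 0.47). A shared genotype effect stays open, since -0.17 lies inside the range of the other relabellings (-0.55 to 0.47). The limit planned beforehand, 5 of 100 as high, was wrong as a ground for excluding it, because a correlation that does not stand out excludes nothing.

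For PTH, the clusters with unadjusted p under 0.05 numbered 443 in Pth-null (highest other split 1696) and 1086 in WT placentas (3220), where 10 splits are again too few for a share under 0.05. Chance was not excluded for PTH averaged over genotypes (599, as large in 65 of 100 splits, highest other 4788) or for the interaction (992, 45 of 100, highest other 4751). Splits with several times the real count point to a structure of the samples, which was not identified: the highest other splits ranked 10 and 2 of 10, 30 of 100 and 25 of 100 by the yolk sac difference, for Pth-null, WT, averaged and interaction. The PTH changes in WT and in Pth-null placentas had r = -0.07.

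Most yolk sac transcripts moved together: the median correlation of a list member with the others, within groups, was 0.95, and 22 of 29 were over 0.5. The other 7 were Col4a1 (0.18), Slc13a4 (-0.13), Sparc (-0.21), Lamb1 (-0.45), Sox17 (-0.45), Pth1r (-0.58) and Nid1 (-0.62). For the 22, this is what a differing share of yolk sac tissue in the dissected samples would give, and Vdr, which followed the list at r = 0.93, may have the same source. The PTH injection stays open as a source (exact two-sided permutation p = 0.32), since a p that misses the threshold does not exclude it.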
